A study of Mus musculus with 12 samples.

How the data were processed

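Chromatin from C2C12 cells, an established mouse myoblast line, was immunoprecipitated with a rabbit antibody against acetylated histone H4 (H4ac) and sequenced, as was input chromatin. The labels describe 12 libraries: 3 H4ac and 3 input libraries from cells transduced with an MLX-DN construct, and the same numbers from cells transduced with an MLX-WT construct. Groups and replicate numbers were taken from the sample titles. The 6 H4ac libraries come with 1 peak list each, and the input libraries entered the comparisons only through the background recovered from those lists. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

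The submitters' processing notes name the mm9 build and the tools CASAVA, BWA 0.5.9-r26, Picard 1.65, SAMtools, R 2.14.0 and MACS2 2.0.9, without their roles or settings. Each deposited list holds the peaks of 1 library, so peaks were called per sample and not on pooled samples. For each peak the authors deposited a fold over background (a ratio), the −log10 of its p-value and of its q-value, and a score, which is the whole part of 10 times the −log10 q in every row. The smallest −log10 q lay between 1.31 and 1.35 in all 6 lists, which corresponds to a q threshold of 0.05. The shortest peak was 250 bp in each list. Fold and q are the authors' own values for a peak and were used to describe, rank or filter peaks within a list. Fold and p also served to recover reads and background, as described next. Folds of single peaks were not tested between the groups. The median fold per library averaged 3.81 ± 0.147 in MLX-DN and 3.83 ± 0.133 in MLX-WT (SD, n = 3; exact permutation test, two-sided, p = 0.70). Caller settings and the handling of duplicate reads are not given in the sources used here.

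Sequencing depth was recovered from the lists. In this caller's output the fold is the ChIP pileup over the background, each with a pseudocount of 1, and the p-value is a Poisson probability of the same pair of values. A scan over ChIP scale factors found for each library 1 factor under which fold and p gave a whole number of ChIP reads for 100.0% of peaks, within 0.001 of the −log10 p. At wrong scale factors 0.233% to 1.73% of peaks matched. The factor was 1 in MLX-WT replicate 3 and 0.848 to 0.938 in the other libraries, where the ChIP reads had thus been scaled down to a separate control. The smallest background in a list is taken here as the genome-wide control level. It came to 3.12 to 3.59 reads per 250 bp window. The labels name input chromatin as the control of the experiment; which library the caller took as control for each list is not given in the sources used here, so the term control background is used below, and it is known only beneath listed peaks. Divided by the scale factor, this level gives the ChIP depth, 3.299 to 3.90 reads per 250 bp window, with the deepest library 1.18 times the shallowest. Mean depth was 3.62 ± 0.279 in MLX-DN and 3.53 ± 0.281 in MLX-WT (SD, n = 3; exact permutation test, two-sided, p = 0.70). Absolute read totals are unknown.

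Peaks of the 6 lists that overlapped or touched were merged into union regions, and a library was said to list a region when 1 of its peaks overlapped it by at least 1 bp. Regions are given in mm9 coordinates counted from 1. Numbers of peaks and covered base pairs were compared on the log2 scale with an exact permutation test of the group labels, two-sided, over 20 assignments. With 3 libraries against 3 this exact test cannot go below p = 0.10. Presence of a single region cannot go below 0.10 either, so no region was tested alone, and counts of regions that separate the groups were set beside the other 9 of the 10 splits of the 6 libraries. The similarity of a pair of lists was the Jaccard index, shared over total covered base pairs. Shares are given with exact 95% binomial intervals, which cover counting error only. The main test, the alternatives and the rule for named regions were fixed before the data were examined. The rule took, for each direction, the 10 regions listed by all 3 libraries of one group and none of the other with the highest value of their lowest within-list percentile of −log10 q, and the 5 regions ranking highest in this way over all 6 libraries. The parts of the rule that name genes were not used, and the same rule was applied to lists of equal length.

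The alternatives were a −log10 q of at least 5, lists cut to the 5385 strongest peaks (the length of the shortest list), peaks covering at least 50% of a region, a reciprocal overlap of 50%, each library left out in turn, and the replicate number as a block. After the data had been seen, 4 more were added: peaks that keep a −log10 p of at least 5 when reads are scaled to the shallowest library, regions within 500 bp joined, only the 11 autosomes whose ratio of control background between the groups lies within 10% of the median, and only the 5 autosomes on which the control background of the groups overlapped. The replicate numbers were not treated as pairs, because no label says what they mark. Comparisons planned on promoters and gene lists were left out, since no mm9 gene annotation was used here; the gene table at hand is of another build and was not used for positions.

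The recovery of reads was tested on simulated peaks at 3 scale factors and returned 100.0% of the read numbers. In simulated lists built from the 31891 regions, with 200 regions seeded into the 3 lists of one group only, all 200 were recovered among 218 counted. The other regions entered each simulated list with the same probability, whereas the real lists held 5385 to 24811 peaks. The simulation thus checks the counting only and does not measure how list length raises the real counts. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.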

Results

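Acetylation of histone H4 was mapped by ChIP-seq in C2C12 mouse myoblasts carrying lentiviral constructs of MLX, a transcription factor that pairs with the glucose-responsive proteins MondoA and ChREBP. H4 acetylation marks active promoters and enhancers. Cells carrying MLX-WT were compared with cells carrying MLX-DN, read here as a dominant-negative form; the labels do not spell the abbreviation out, and one of their fields calls these samples MLX down. Peak names in the lists carry a tag for glucose being present. Each group had 3 H4ac libraries, and the comparison asks whether the distribution of acetylated H4 differs with the form of MLX expressed. The ChIP depth recovered from the lists was 3.34, 3.90 and 3.63 reads per 250 bp window in MLX-DN replicates 1, 2 and 3 and 3.46, 3.84 and 3.299 in MLX-WT replicates 1, 2 and 3.

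H4ac peaks were more numerous in cells carrying MLX-DN. The 3 MLX-DN libraries listed 15201, 24811 and 16898 peaks and the MLX-WT libraries 5385, 13652 and 9422, in the order of replicates 1 to 3. The mean was 18970 ± 5129 peaks in MLX-DN against 9486 ± 4134 in MLX-WT (SD, n = 3), a geometric mean ratio of 2.10. Listed peaks covered 9.56 ± 3.10 Mb of the genome in MLX-DN and 4.29 ± 2.12 Mb in MLX-WT, a ratio of 2.36. Peaks longer than 1 kb made up 5.88% ± 1.53 of the MLX-DN lists and 2.86% ± 1.32 of the MLX-WT lists. The median peak width was 413 ± 14.8 bp against 380 ± 19.4 bp. The lowest MLX-DN library exceeded the highest MLX-WT library in peak number and covered length (exact permutation test, two-sided, p = 0.10 for each, the smallest value this design allows). The widths overlapped between the groups (exact p = 0.20). At equal depth the ratio of peak numbers was 2.06.

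**Figure D1:**
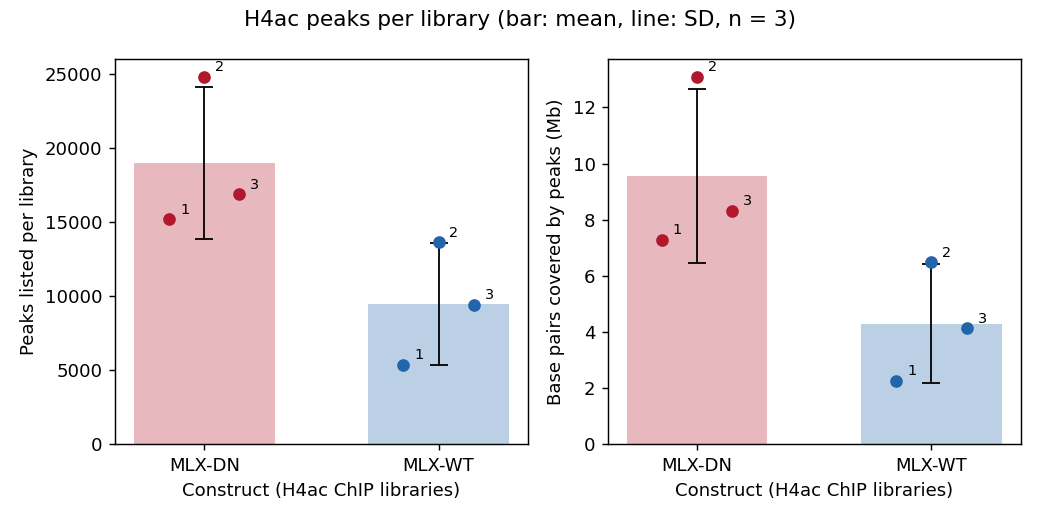
Number of H4ac peaks per library (left panel, peaks) and base pairs they cover (right panel, Mb) for cells carrying MLX-DN or MLX-WT; points are libraries marked with their replicate number, bars are means and lines SD (n = 3). All 3 MLX-DN libraries, from 15201 peaks upward, lie above the highest MLX-WT library, with 13652 peaks.

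In the full lists, most regions listed for the MLX-WT cells were listed for the MLX-DN cells too, and the reverse held for fewer; the lists differed in length, and at equal length the shares were close to each other. The 6 lists merged into 31891 regions, of which 3107 were listed by all 6 libraries and 13692 by a single one. At least 2 of 3 libraries listed 15526 regions in MLX-DN and 7551 in MLX-WT, and 6631 regions met this in both groups. These shared regions were 87.8% of the MLX-WT set (exact 95% interval 87.1 to 88.5) and 42.7% of the MLX-DN set (41.9 to 43.5), intervals that leave out the spread between libraries. Among the 5385 strongest peaks of each library the shares were 65.1% and 62.4%. The 42.7% became 37.2%, 22.9% and 26.3% without MLX-WT replicates 1, 2 and 3. Without MLX-DN replicates 1, 2 and 3 it became 48.2%, 55.2% and 51.0%. The 87.8% became 89.0%, 94.4% and 93.3%, and 79.5%, 72.0% and 78.3%, in the same order. Where peaks had to cover 50% of a region, the 42.7% became 27.0% and the 87.8% became 79.1%. With 1 library left out, both remaining libraries of its group had to list a region, which by itself shrinks the set of that group. All 3 MLX-DN libraries and no MLX-WT library listed 1945 regions, and the opposite pattern was found at 53 regions. The other 9 splits of the 6 libraries separated at most 566 regions, against 1998 for the split by construct. That split also parts the 3 longest lists from the 3 shortest, so list length by itself raises its count. The requirement that every library of a group lists a region makes these counts depend on single libraries: the 1945 became 3840 without MLX-DN replicate 1, 3230 without MLX-DN replicate 3 and 3207 without MLX-WT replicate 2. The 53 became 126 without MLX-DN replicate 2, 251 without MLX-WT replicate 1 and 96 without MLX-WT replicate 3, and the 6631 became 3570 without MLX-WT replicate 2 and 4097 without MLX-WT replicate 3.

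**Figure D2:**
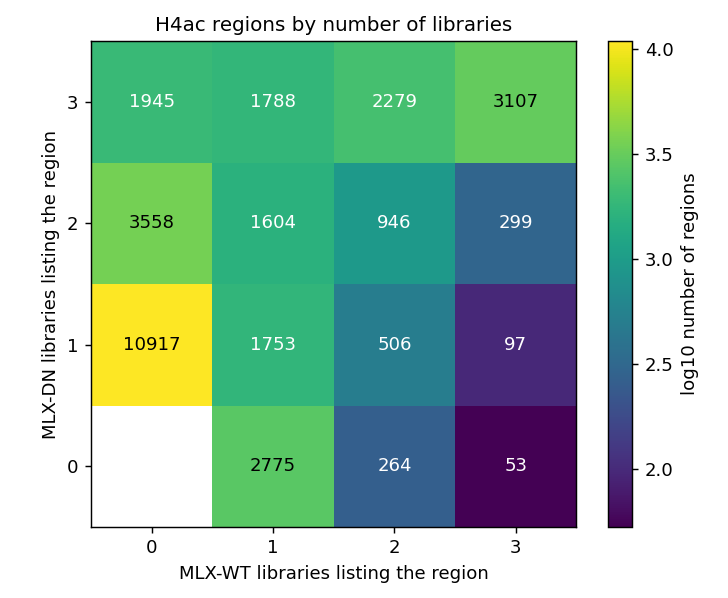
Number of merged H4ac regions by how many of the 3 MLX-WT libraries (horizontal axis) and of the 3 MLX-DN libraries (vertical axis) list them; colour gives the log10 number and each cell the number itself. The upper left cell, regions of all MLX-DN and no MLX-WT library, holds 1945 regions and the lower right cell 53.

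Regions shared by all 6 libraries ranked high within the lists, and those of one group had a middle rank. Shared regions stood at a median percentile of 86.9 within the MLX-DN lists and 76.2 within the MLX-WT lists, by the authors' −log10 q. The 1945 MLX-DN regions had a median percentile of 50.01 and the 53 MLX-WT regions one of 49.1. Among the MLX-DN regions 44 ranked in the top 25% of all 3 MLX-DN lists, and among the MLX-WT regions 1 did so in its own lists. A peak of the other group lay within 1 kb of 537 MLX-DN regions (27.6%) and of 21 MLX-WT regions (39.6%). Of the strongest 25% of peaks, 85.9% to 90.5% in the MLX-DN lists were listed in at least 1 library of the other group, as were 98.4% to 99.4% in the MLX-WT lists. Of the weakest 25% the shares were 23.1% to 39.1% and 69.3% to 91.8%.

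The 5 regions highest in rank over all 6 libraries were on chromosome 2 from 156005112 to 156005946, chromosome 15 from 78857824 to 78859382, chromosome 18 from 65739836 to 65741792, chromosome 13 from 58502555 to 58504878 and chromosome 9 from 71332925 to 71333866 (mm9). Their lowest percentile in any list was 99.7, with folds between 5.74 and 13.8. The strongest region of all MLX-DN and no MLX-WT library was on chromosome 8 from 93947430 to 93948353, with a lowest percentile of 97.9 in the MLX-DN lists and folds of 5.78 to 6.09, although an MLX-WT peak lay within 1 kb of it. On chromosome 9, the region from 119486632 to 119488491 was 1860 bp wide, with folds of 4.95 to 5.87 and no MLX-WT peak within 1 kb. The region on chromosome 5 from 108188658 to 108189321 had folds of 6.26 to 8.96, and that on chromosome 3 from 89383050 to 89383993 folds of 5.28 to 6.38, again with no MLX-WT peak within 1 kb. Of the 10 MLX-DN regions named by the rule, 5 were on chromosome 8 and 8 were on the 7 chromosomes whose control background was higher in MLX-DN, described below. The remaining 2 were on chromosome 17 from 44637752 to 44639159, with an MLX-WT peak within 1 kb, and on chromosome 19 from 25501174 to 25502869, with none.

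The strongest MLX-WT region absent from all MLX-DN lists was on chromosome 15 from 11104017 to 11104805, with a lowest percentile of 80.3 in the MLX-WT lists and folds of 3.31 to 4.93. It was followed by chromosome 17 from 31684498 to 31685004, with folds of 5.21 to 6.18. On chromosome 10 the region from 98569792 to 98570282 had folds of 4.32 to 5.20 and an MLX-DN peak within 1 kb, and the region from 70621918 to 70622711 folds of 3.92 to 7.79 and none. On chromosome 7 the region from 108092081 to 108093023 had folds of 4.32 to 5.87. Of the 10 MLX-WT regions named by the rule, 4 were on chromosome 10 and 2 on chromosome 15, and another was on chromosome 14. On each of these chromosomes control background was higher in every MLX-WT library than in every MLX-DN library. The MLX-DN over MLX-WT ratio was 0.924 on chromosome 10, 0.791 on 15 and 0.950 on 14. The others were on chromosomes 7 and 17, where the groups overlapped in control background. None was on the 7 chromosomes with higher control background in MLX-DN.

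With lists of equal length the groups still differed in which regions ranked highest. Among the 5385 strongest peaks of each library, 231 regions were in all MLX-DN and no MLX-WT list and 159 in all MLX-WT and no MLX-DN list. The split by construct separated 390 regions, against at most 134 for the other 9 splits. The full lists of the other group held 157 of the 231 and 141 of the 159, so 74 MLX-DN and 18 MLX-WT regions were in no list of the other group at any rank. The strongest of the 231 was again the region on chromosome 8 from 93947430, followed by chromosome 4 from 138648044 to 138649601, with folds of 5.57 to 10.3. The strongest of the 159 were on chromosome 15 from 58247042 to 58247579, with folds of 3.56 to 5.05, and on chromosome 2 from 44972188 to 44972994, with folds of 4.91 to 6.70. In the full lists a peak of the other group lay within 1 kb of all 10 MLX-DN regions named by the rule at equal length and of 8 of the 10 MLX-WT regions. The equal-length MLX-DN peaks covered 1.40 times the base pairs of the MLX-WT peaks. On average, libraries of one group resembled each other more than those of the other group: in the full lists the Jaccard index averaged 0.400 ± 0.0181 within MLX-DN, 0.306 ± 0.0477 within MLX-WT and 0.266 ± 0.0679 between groups (SD over 3, 3 and 9 pairs). Single pairs overlapped: in the full lists MLX-WT replicate 2 had an index of 0.260 with MLX-WT replicate 1 and 0.356 with MLX-WT replicate 3, against 0.350, 0.321 and 0.340 with MLX-DN replicates 1, 2 and 3. At equal length these were 0.334 and 0.365, against 0.342, 0.333 and 0.327. The mean within minus the mean between was 0.0867 with all peaks and 0.0651 at equal length, each the highest of the 10 splits (exact permutation test, one-sided, p = 0.10). With all peaks the difference was 0.0516 without MLX-DN replicate 2 and 0.145 without MLX-WT replicate 2, and 2 of the 10 splits were as large when any 1 MLX-DN library was left out.

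Acetylated peaks were spread differently over the chromosomes in the 2 groups. In equal-length lists chromosome 15 held 7.84% ± 0.151 of MLX-WT peaks and 5.98% ± 0.219 of MLX-DN peaks, and chromosome 11 held 10.1% ± 0.644 and 8.77% ± 0.147 (SD, n = 3). Chromosome 5 held 4.98% ± 0.129 of MLX-WT and 6.33% ± 0.141 of MLX-DN peaks, and chromosome 4 held 5.62% ± 0.0284 and 6.93% ± 0.207. Of the 20 chromosomes, 7 had a higher share in every MLX-WT library (2, 7, 10, 11, 14, 15 and 19) and 8 in every MLX-DN library (1, 3, 4, 5, 8, 9, 12 and 17). Each of these 15 had an exact p of 0.10 and an adjusted p of 0.133 over the 20 chromosomes, where chance separates 10% of chromosomes; no other split of the libraries separated more than 2. In the full lists 17 chromosomes separated the groups (adjusted p = 0.118): chromosomes 6 and 18 joined those with a higher share in MLX-WT and 16 and X those with a higher share in MLX-DN, while chromosome 7 (exact p = 0.20) and chromosome 8 (5.54% ± 0.0472 in MLX-DN, 5.51% ± 0.130 in MLX-WT, exact p = 0.80) no longer did.

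The control background also differed between the groups by chromosome. At the 3107 regions listed by all 6 libraries, and relative to the library mean, it was 1.14 ± 0.0239 in MLX-DN and 1.45 ± 0.0308 in MLX-WT on chromosome 15, and 1.33 ± 0.00655 and 1.05 ± 0.0103 on chromosome 8 (SD, n = 3). On chromosomes 1, 3, 4, 5, 8, 9 and 12 the MLX-DN level was 1.13 to 1.26 times the MLX-WT level, and on chromosome 15 it was 0.791 times (exact permutation test, two-sided, p = 0.10 for each of these 8, adjusted p = 0.133). On the other 11 autosomes the ratio lay between 0.918 and 0.998, and on 6 of them (6, 10, 11, 14, 18 and 19) every MLX-WT library was above every MLX-DN library, with the same exact p of 0.10 and adjusted p of 0.133. On the remaining 5 (2, 7, 13, 16 and 17) the groups overlapped, and the ratio of peak numbers there was 2.03. Chromosome X had 11 such regions and was not classed. Its ratio was 0.862, with every MLX-DN library below every MLX-WT library (exact p = 0.10, adjusted p = 0.133), while it held 0.890% ± 0.0425 of MLX-DN and 0.651% ± 0.184 of MLX-WT peaks in the full lists (exact p = 0.10) and 0.508% ± 0.134 and 0.532% ± 0.0387 at equal length (exact p = 1.0). The ratio of peak numbers between the groups was 2.43 on the 7 chromosomes with higher background in MLX-DN, 1.62 on chromosome 15 and 1.96 on the 11 others. On chromosome 15 the groups overlapped, with 843 peaks in the lowest MLX-DN library and 980 in the highest MLX-WT library (exact p = 0.20), and on the other sets they did not (exact p = 0.10 for each). Of the regions listed by all MLX-DN libraries, no MLX-WT library listed 26.04% on the 7 chromosomes (exact 95% interval 24.6 to 27.5), 18.7% on the 11 others (17.7 to 19.9) and 13.4% on chromosome 15 (10.7 to 16.6). Of the 53 MLX-WT regions, 31 were on the 11 autosomes, 12 on the 7 and 10 on chromosome 15.

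**Figure D3:**
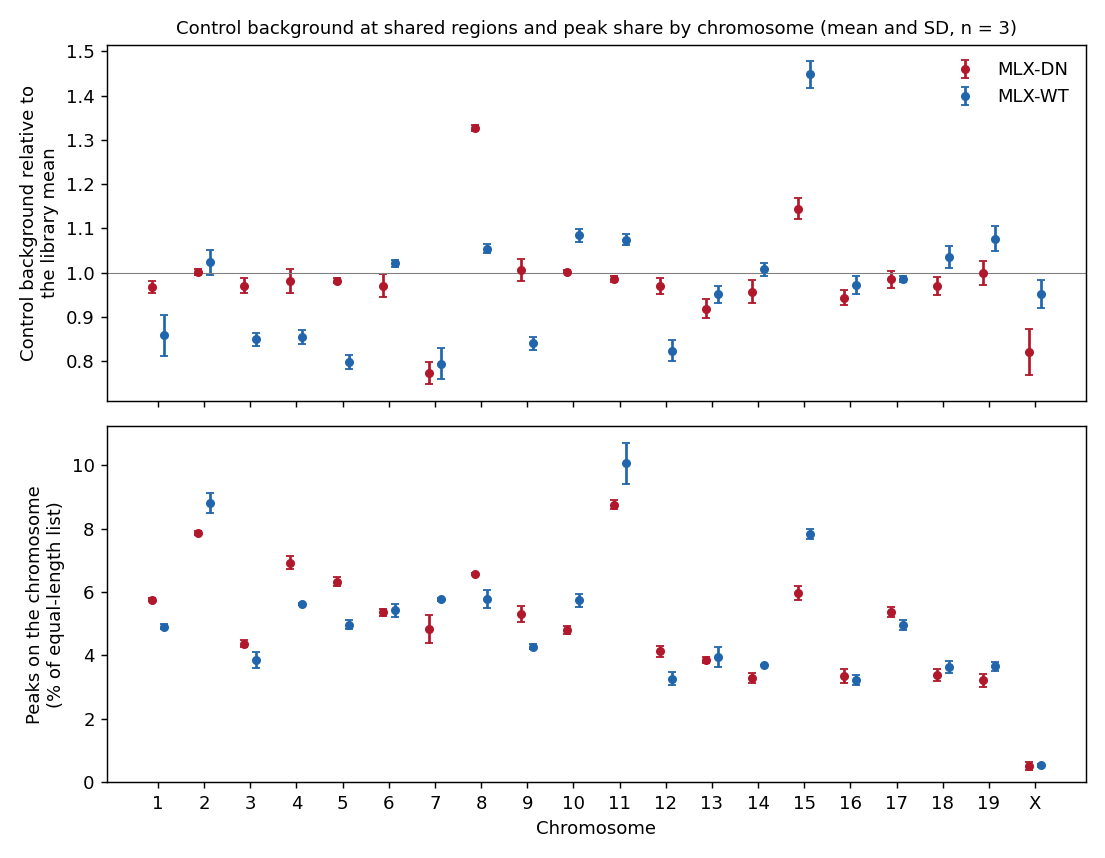
Control background at the 3107 regions listed by all 6 libraries, relative to the library mean (upper panel, ratio), and percent of the 5385 strongest peaks on each chromosome (lower panel, percent) for MLX-DN and MLX-WT; points are means and lines SD (n = 3). Chromosome 15 is high in MLX-WT in both panels, and chromosomes 1, 3, 4, 5, 8, 9 and 12 are higher in MLX-DN in both.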

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

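Not every alternative bears on every measure. Those fixed in advance or added after seeing the data left the direction of peak number, covered length and similarity as it was wherever these were compared, and none could pass 0.05. The cover of 50% of a region and the joining within 500 bp were compared on region counts only. The log2 difference ranged from 0.71 to 1.38 for peak number, from 0.48 (equal list length) to 1.60 for covered length, and the similarity difference from 0.0516 to 0.145. With the replicate number as a block the log2 differences were again 1.07 and 1.24 (exact sign-flip test, p = 0.25). This is the smallest p that 3 pairs allow. Same-numbered deviations from the group means correlated across regions at −0.0593, −0.0596 and 0.000683, and no library correlated best with its own number. Peak numbers nevertheless rose in the order of replicates 1, 3 and 2 in both groups. They were 15201, 16898 and 24811 in MLX-DN and 5385, 9422 and 13652 in MLX-WT. Whether the numbers mark pairs thus stays open. Counts of regions moved by over 1.5 times, by construction where fewer peaks, libraries or chromosomes enter. Regions of all MLX-DN and no MLX-WT library numbered 1265 at −log10 q of at least 5, 231 at equal list length, 933 on the 11 near-median autosomes and 483 on the 5 autosomes of overlapping background (both added), and 2069 to 3840 with 1 library left out. Regions of all MLX-WT and no MLX-DN library numbered 30, 159, 31, 11 and 65 to 251. Regions in at least 2 of 3 libraries of both groups numbered 2935 at equal list length, 3643 where peaks had to cover 50% of a region, 3868 on the 11 autosomes, 1782 on the 5 and 3570 to 6009 with 1 library left out. Equal list length reduced the excess of MLX-DN over MLX-WT regions from 1945 against 53 to 231 against 159, since equal lists remove the difference in list length. At equal depth and with regions within 500 bp joined (both added) all counts stayed within 1.5 times. The alternatives fixed for promoters and gene lists were not run, because no mm9 annotation was used here. The background of 3.12 to 3.59 control reads per 250 bp limits detection: no peak rested on fewer than 13 ChIP reads at its summit, so weaker acetylation was not detectable at this depth.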

Other observations

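The tests of depth, ChIP enrichment, the relations of control background with peak share and with ChIP reads, the other splits, and the 5 autosomes were chosen after the results they bear on had been seen; the 11 autosomes were chosen after the background had been seen, but what they would show for peak numbers and separated regions was written down before those results, as were the tests along chromosomes and of the choice of regions.

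Chromosome 7 had the lowest control background at shared regions in both groups, 0.772 ± 0.0248 of the library mean in MLX-DN and 0.794 ± 0.0348 in MLX-WT (SD, n = 3). In MLX-WT chromosome 5 was close to it, at 0.798 ± 0.0159. Chromosome 15 had a high control background in both groups. Regions found in 1 library only were most frequent in MLX-DN replicate 2, with 7122 regions or 30.1% of those it listed, and least frequent in MLX-WT replicate 1, with 126 regions or 2.49%.

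The greater number of H4ac peaks with MLX-DN is not accounted for by sequencing depth, since the ratio of peak numbers was 2.06 at equal depth and 2.10 before. Chromosome dosage is not the whole cause: on the 11 autosomes with a near-median control background ratio the ratio of peak numbers was 1.96, and on the 5 of them whose background overlapped between the groups it was 2.03, with more peaks in each MLX-DN library than in each MLX-WT library on both sets. ChIP reads at the summit were also compared at the 1834 regions of the 11 autosomes listed by all 6 libraries. They were taken per read of the genome-wide level of the library, not of the control background beneath each region. This ratio was 0.29 higher on the log2 scale in MLX-DN (3.84 ± 0.03 against 3.56 ± 0.06, SD, n = 3, exact permutation test, two-sided, p = 0.10). A summit is a maximum, however, and these regions were chosen for being called in every list. A better yield of the immunoprecipitation in MLX-DN and a genome-wide difference in H4 acetylation between the groups both predict a higher ratio. They cannot be told apart, because no spike-in or other external scale was used here. No cells free of either construct were among the samples. A gain of acetylation with MLX-DN thus cannot be told from a loss with MLX-WT either. The real split separated 1998 regions and the highest other 566, so 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. The real split also parts the longer lists from the shorter ones, which by itself raises its count.

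For the uneven spread over chromosomes, a candidate explanation is that the MLX-DN and MLX-WT cell populations differ in chromosome copy number, as a culture of an aneuploid line may. Across the 19 autosomes the MLX-DN over MLX-WT ratio of control background rose with the same ratio of peak shares in equal-length lists (Spearman's rho = 0.886, Pearson's r = 0.911, permutation p = 1e-05 for each, the smallest the permutations can give, adjusted p = 1.25e-05 over 5 relations; r = 0.931 without chromosomes 5 and 8), and less closely in the full lists (rho = 0.796, adjusted p = 0.00011; r = 0.833, adjusted p = 2e-05; r = 0.929 without chromosomes 5 and 8), chromosomes not being independent replicates; chromosome X, left out, ran the other way in the full lists. The background ratio held along chromosomes, with rho = 0.889 between their proximal and distal parts, which argues against a few loci as its source. At 9272 other regions listed in both groups it held too, with rho = 0.914 against the regions listed by all 6 libraries. The background ratio thus did not rest on listing by all 6 libraries. Both sets hold listed regions only, so an effect of choosing listed regions cannot be excluded in this way. A bias of the control libraries alone would leave ChIP reads as they are and lower peak shares where the background is higher. ChIP reads at the summits of the 3107 regions followed the background ratio (rho = 0.902, r = 0.920, r = 0.977 without chromosomes 5 and 8, adjusted permutation p = 1.25e-05 for rho and r). These regions were chosen for being called in every list, which asks for more reads where the background is higher. The relation of reads alone thus cannot exclude such a bias. Peak shares, however, rose with the background ratio across autosomes. Chromosome 8 departed from this in the full lists, with the highest ratio, 1.26, but shares of 5.54% in MLX-DN and 5.51% in MLX-WT. Whether copy number differs stays open, since the background was seen only beneath listed peaks and a bias common to the control and ChIP libraries of a group, as with GC content, was not tested.

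The third pattern is the set of regions that separate the groups at equal list length, 390 against at most 134 for the other 9 splits; 1 of the 10 splits, the real one, gave as many, and the splits are again too few for a share under 0.05. The forecast for a uniform difference in yield together with chromosome dosage was that the real split would not stand out on the 11 autosomes of near-median control background ratio. There, with 3172 peaks taken per library, it separated 196 regions against at most 84, a ratio of 2.33. On the 5 autosomes of overlapping background, with 1445 peaks per library, it separated 99 against at most 42, a ratio of 2.36. These values argue against chromosome dosage alone as the full cause. They cannot decide on a difference in yield, because equal list length does not remove it. Lists cut to equal length reach lower ranks of the shorter lists. The equal-length MLX-DN peaks also still covered 1.40 times the base pairs of the MLX-WT peaks. What sets these regions apart stays open, a difference in yield included. An effect of the form of MLX at single loci, dosage changes of parts of chromosomes and differences in how the 2 groups were handled were not tested.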
